A study of Mus musculus with 14 samples.

How the data were processed

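The series holds 14 chromatin immunoprecipitation libraries (ChIP-seq, in which DNA bound by a protein or histone mark is pulled down with an antibody and sequenced) from mouse. Per the labels, 8 libraries came from tumour cells lacking p53 and p18, and 6 from neurospheres of the same genotype, which are floating cultures of neural cells. The tumour cells were labelled Cas9 (control) or Ezh2 knockout, and each kind was profiled for H3K27me3, H3K27ac and H3K4me3 beside an input library. The neurospheres were profiled with a Cas9 antibody in cells labelled U6, Suz12F1 and Suz12F2, with a Gfi1 antibody in cells labelled Cas9 and Suz12F2, and with 1 input library. The labels do not say what U6, F1 and F2 stand for, so each label was kept as a group of its own. Groups were taken from the titles, genotype and antibody labels, and every group held 1 library.

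The files analysed were 11 lists of enriched regions, each called by the authors on 1 library. The 3 input libraries were not used here, and which of them served as background for each list is not given in the sources used here. Per the submitters' processing notes, BWA 0.5.9-r26, Picard, SAMtools, R 2.14.0, SICER 1.1 and genome build mm9 were used, named without role or order. The tumour H3K27me3 lists and the 5 neurosphere lists hold islands, meaning runs of enriched windows joined across gaps. Per the names the authors gave these 7 deposited lists, the window was 200 bp, the gap 600 bp and the false discovery rate 0.00001. The starts of these islands lie on a 200 bp grid, and their ends name the last base counted from 0, so 1 bp was added to each end. The H3K27ac and H3K4me3 lists hold narrow peaks, whose caller and threshold are not given in the sources used here.

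Each region in the deposited lists carries a score from the authors, whose meaning the files do not state. In the island lists it is a whole number that grows with island length. It was used to rank regions within 1 list and never to compare lists. Read depth is unknown, since the lists hold no library totals, and a list can be longer because its library was deeper or cleaner. The 6 tumour lists number their regions, and some numbers were not analysed here: 71, 375 and 486 of the H3K27me3, H3K27ac and H3K4me3 lists of Cas9 cells, and 105, 363 and 467 of those of the knockout.

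From these lists the number of regions, the covered length and the overlaps were computed with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. A region counted as overlapped when it shared at least 1 bp with a region of the other list. Shares carry Wilson 95% intervals, which cover counting error only and neither biological nor technical variation. With 1 library per group no test across samples was possible, and no p-value was computed across regions. To show how many overlaps arise by position alone, regions were placed at random 1000 times on their own chromosome, between the lowest start and highest end seen in any list. Folds are the observed number over the median placement. These spans are not the full chromosomes, and assembly gaps were not masked. Since marks cluster in the same neighbourhoods, each region was also shifted at random by up to 500 kb. These shifts were drawn 1000 times for marks within H3K27me3 regions and for the test of spreading next to former H3K27me3 regions. For all other pairs of lists they were drawn 100 times.

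Overlap counts were checked against bedtools 2.31.1 for 220 combinations of list pairs and overlap rules, of which 0 differed. On simulated data built from the 14107 H3K27me3 regions of Cas9 cells, all 2000 of 2000 planted overlaps were recovered. The fold over placement was 1.08 with none planted and 6.01 with them.

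The comparisons, the main rule for each and the alternatives were fixed before the data were examined. The H3K27me3 length classes and the H3K27ac calls at H3K4me3 peaks grouped by their other marks were not among these comparisons. Alternatives were 50% cover of a region, the upper 50% of scores, lists trimmed to equal numbers by score, merging within 5 kb, autosomes alone, regions of at least 1 kb, circular shifts and removal of regions found with the Cas9 antibody. The shifts of up to 500 kb, the equal numbers of H3K27ac peaks at H3K4me3 peaks, the equal numbers of Cas9 antibody regions, the removal of Cas9 antibody regions from tumour lists and their removal without the Suz12F1 list were added after seeing the data. Counts of peaks inside named H3K27me3 regions, the peak widths and the split of H3K27ac peaks by score quartile were likewise added after the main results were seen.

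Regions named in the text were drawn from sets chosen by a rule fixed beforehand: per comparison, the 5 regions with the highest score that were called in the first list alone, in the second alone and in both. From some of these sets only the highest-scoring regions are named. Exceptions are stated where they occur. A gene annotation of build mm9 was not used here, so regions are given by coordinates, counted from 1, without gene names, and the planned analysis of promoters and gene lists was not run. The transcript or protein level of the targeted gene was not analysed here, so the knockout was checked through H3K27me3 alone.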

Results

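Regions of enrichment were compared for 3 histone marks in Myc-driven medulloblastoma cells with and without Ezh2, and for 2 antibodies in neurospheres. Ezh2 is the enzymatic subunit of Polycomb repressive complex 2, which methylates lysine 27 of histone H3 and is linked to gene silencing. H3K27ac marks active promoters and enhancers, and H3K4me3 marks promoters. There was 1 library per group, so no value below has a replicate error. Intervals are Wilson 95% intervals for counting error, all positions are in build mm9, and read depth is unknown.

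The first comparison asked what Ezh2 loss did to H3K27me3 in tumour cells. H3K27me3 covered 71.4 Mb in Cas9 cells and 18.6 Mb in the Ezh2 knockout, a ratio of 0.261. The list held 14107 regions in Cas9 cells and 5312 in the knockout, and the mean region length was 5062 bp and 3503 bp. The longest region measured 141 kb in Cas9 cells. Of the Cas9 regions, 1680 were overlapped by a knockout region, or 11.9% (11.4 to 12.5), and 12427 were called in Cas9 cells alone. This share was 5.79-fold over random placement and 2.07-fold over shifts of up to 500 kb. Of the knockout regions, 1815 overlapped a Cas9 region, or 34.2% (32.9 to 35.5), and 3497 were called in the knockout alone.

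**Figure D1:**
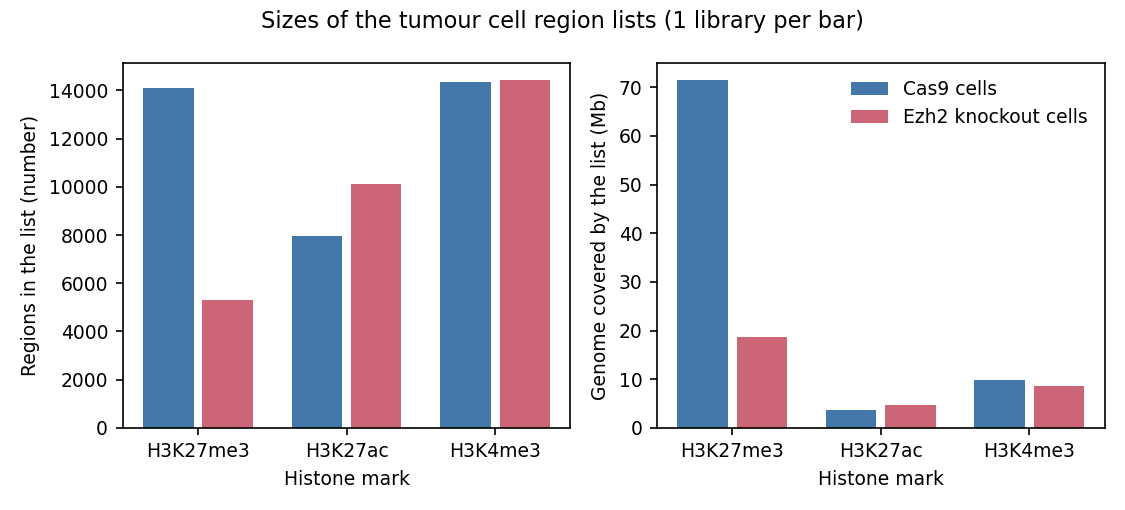
Number of regions (left) and genome covered in Mb (right) for 3 histone marks in Cas9 cells (blue) and Ezh2 knockout cells (red), each bar being 1 library without error. H3K27me3 went from 71.4 to 18.6 Mb, H3K27ac from 3.64 to 4.67 Mb and H3K4me3 from 9.74 to 8.57 Mb.

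Long H3K27me3 regions were overlapped in the knockout more often than short ones. Of regions under 2 kb, 7.98% (6.60 to 9.63) were overlapped, against 24.0% (21.4 to 26.7) of those from 10 to 20 kb and 46.3% (40.0 to 52.8) of the 231 regions of 20 kb or more. A longer region meets another by chance more often, and the random placements followed the same order, from 1.29% to 6.06%. The fold over placement was 6.19 in the shortest class, 5.57 from 2 to 5 kb and 7.64 in the longest. Knockout regions covered 10.4% of the length of the regions of 20 kb or more.

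**Figure D2:**
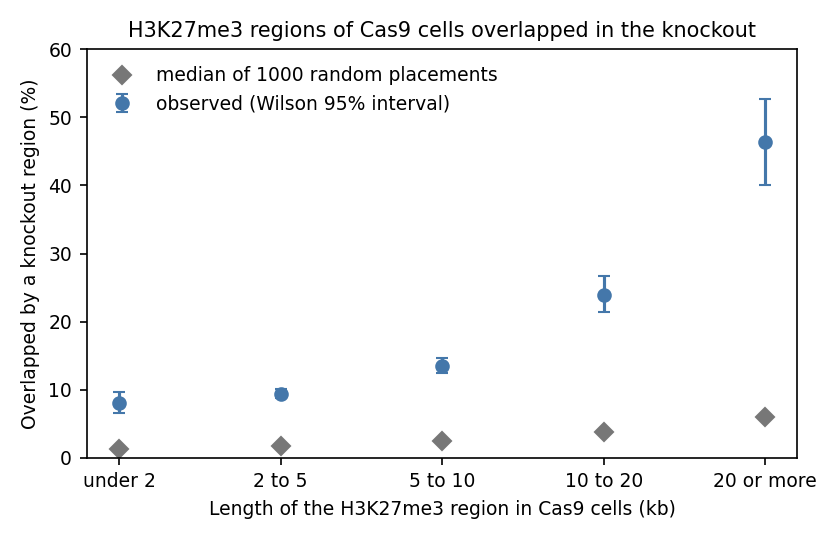
Percent of Cas9 H3K27me3 regions overlapped by a knockout H3K27me3 region (vertical axis) by length of the Cas9 region in kb (horizontal axis). Blue points are observed shares with Wilson 95% intervals and grey diamonds are medians of 1000 random placements, and the observed share goes from 7.98% to 46.3%.

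The 4 H3K27me3 regions with the highest scores in Cas9 cells lay on chromosome 6 from 52099401 to 52237200, chromosome 15 from 102736601 to 102877600, chromosome 2 from 74516201 to 74611600 and chromosome 11 from 96108401 to 96182800. Each counted as called in both cells, yet knockout regions covered 7.55%, 7.09%, 9.64% and 6.72% of their lengths. In Cas9 cells the 4 regions held 1 H3K4me3 peak and 0 H3K27ac peaks. In the knockout they held 45 H3K4me3 peaks, of which 44 were called in the knockout alone, and 20 H3K27ac peaks, of which 20 were called in the knockout alone. These peak counts were made after the lists had been compared. The fifth region, on chromosome 5 from 33816001 to 33894000, held 0 peaks of either mark in either kind of cell. The highest-scoring regions called in Cas9 cells alone were on chromosome 11 from 96183601 to 96238400 and from 96038801 to 96079600, chromosome 1 from 78183601 to 78218600, chromosome 19 from 45210801 to 45248800 and chromosome 9 from 107242201 to 107294000. Together these 5 held 2 H3K4me3 peaks in Cas9 cells and 12 in the knockout. The first of the 5 starts just after the end of the chromosome 11 region called in both cells, at 96182800. Its call in Cas9 cells alone thus depends on the gap allowed within islands.

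**Figure D3:**
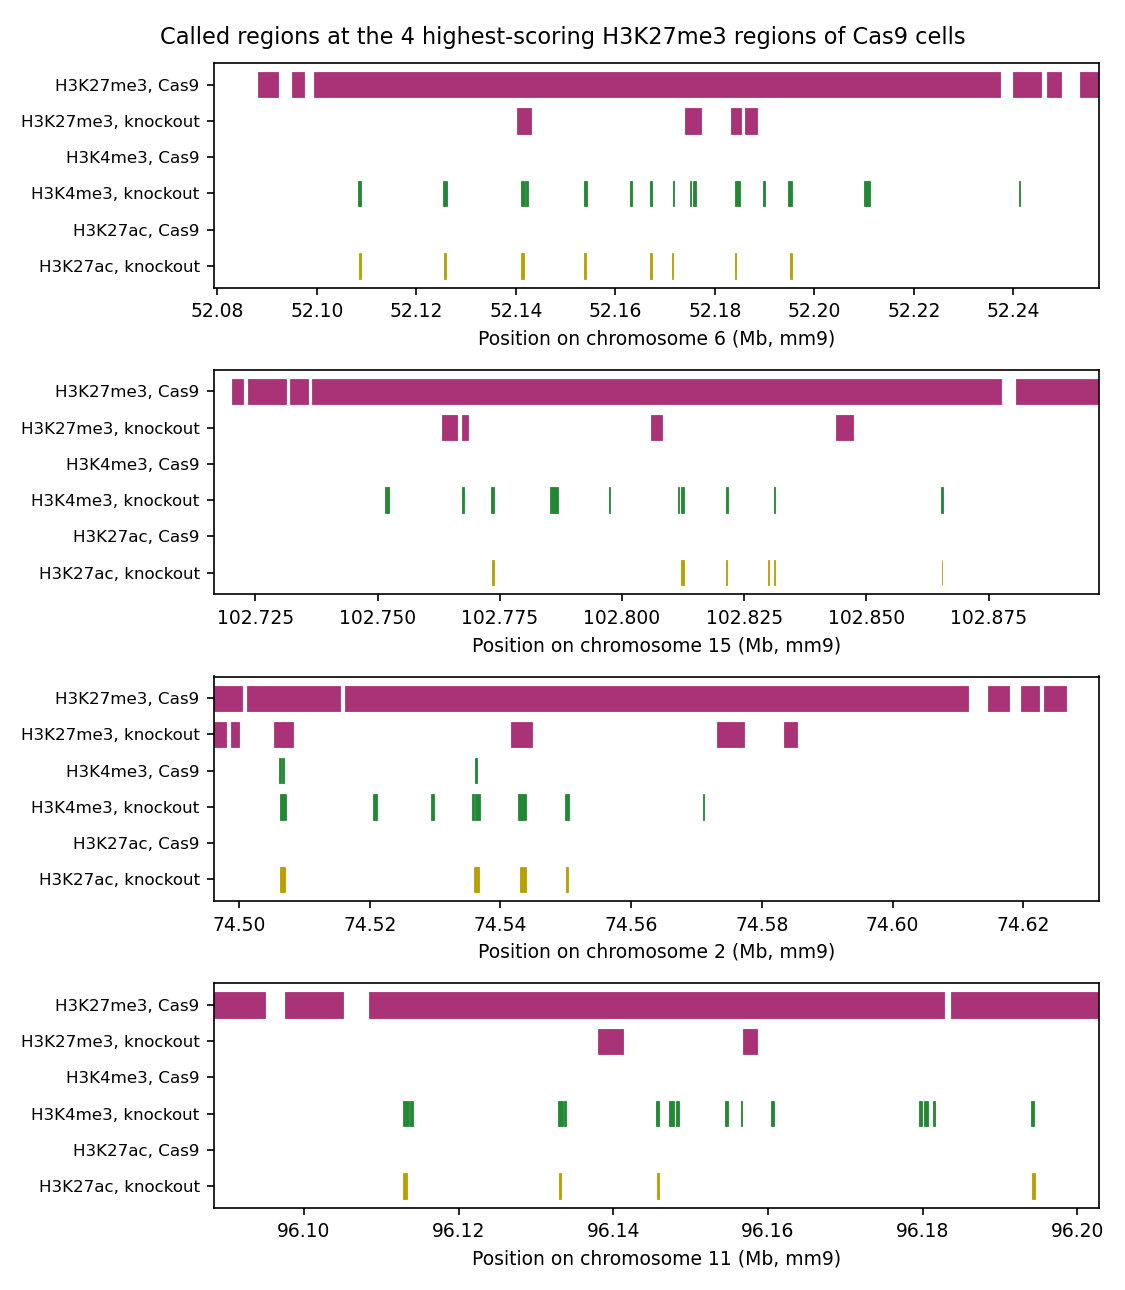
Called regions along the 4 highest-scoring H3K27me3 regions of Cas9 cells with 20 kb either side (horizontal axis, position in Mb), 1 row per mark and kind of cell. Boxes are called regions to scale, and inside the 4 regions the knockout rows hold 45 H3K4me3 and 20 H3K27ac peaks where the Cas9 rows hold 1 and 0.

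Regions called in the knockout alone were shorter and held few active marks. Their mean length was 3293 bp, and 10 of 3497 held an H3K27ac peak of the knockout alone, or 0.286% (0.155 to 0.526), against a median of 15 (5 to 29) after random placement. For H3K4me3 peaks of the knockout alone the number was 9 against 7 (1 to 16), so that neither left the range of placement. Peaks of H3K27ac and H3K4me3 called in both kinds of cell lay in 18 and 32 of them, 0.474-fold and 0.492-fold of placement. The 5 with the highest scores lay on chromosome X from 166407601 to 166420200, chromosome 4 from 145661201 to 145678000 and from 146707601 to 146715400, chromosome 13 from 13015001 to 13028600 and chromosome 6 from 113815201 to 113831000. They held 0 H3K4me3 and 0 H3K27ac peaks in either kind of cell. When 50% of a region had to be covered, the overlapped share of Cas9 regions was 6.40%. With lists trimmed to equal numbers by score, the covered length ratio was 0.414 and the overlapped share of knockout regions was 20.5%.

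H3K27ac was called at more places in the knockout, and most places of the Cas9 cells recurred. The lists held 7951 peaks in Cas9 cells and 10112 in the knockout, covering 3.64 and 4.67 Mb, a ratio of 1.28. Of the Cas9 peaks 91.4% (90.7 to 92.0) overlapped a knockout peak, and of the knockout peaks 71.9% (71.0 to 72.8) overlapped a Cas9 peak. This left 685 peaks in Cas9 cells alone and 2843 in the knockout alone. Most of the latter, 82.8% (81.4 to 84.1), lay at an H3K4me3 peak that Cas9 cells already had. This was less than the 97.1% (96.7 to 97.4) of knockout peaks shared with Cas9 cells. The highest-scoring peak of the knockout alone lay on chromosome 6 from 86476657 to 86477411. The next 4 lay on chromosome 7 from 19904824 to 19905502 and chromosome 1 from 186823065 to 186823884, from 9787930 to 9788699 and from 33964416 to 33965146, and all 4 overlapped H3K27me3 regions of Cas9 cells. Of the 5 highest-scoring peaks of Cas9 cells alone, 1 did, on chromosome 15 from 61819094 to 61819725. The highest-scoring peak called in both lay on chromosome 5 from 28643110 to 28644314.

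H3K4me3 peaks were about as many in both kinds of cell and narrower in the knockout. There were 14363 peaks in Cas9 cells and 14417 in the knockout, with mean lengths of 678 and 594 bp, so that the covered length was 9.74 and 8.57 Mb, a ratio of 0.879. Of the Cas9 peaks 85.4% (84.9 to 86.0) were overlapped, as were 90.2% (89.7 to 90.6) of the knockout peaks. Cas9 cells alone had 2090 peaks and the knockout alone 1418. Of the 5 highest-scoring peaks of the knockout alone, 3 lay inside the chromosome 6 region above, at 52141115 to 52141868, 52194735 to 52195528 and 52108348 to 52108927. The others lay on chromosome 8 from 125951826 to 125952013, in another H3K27me3 region of Cas9 cells, and chromosome 6 from 38484823 to 38485232, outside such regions. The highest-scoring peak of Cas9 cells alone lay on chromosome 14 from 120877604 to 120878436, and the highest-scoring shared peak on chromosome 5 from 137951331 to 137952657. The ratio of peak numbers, 1.00, has no firm direction: it was 0.653 for peaks of at least 1 kb and 0.996 outside Cas9 antibody regions. Among peaks of at least 1 kb, 55.2% of those of Cas9 cells were overlapped.

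Whether active marks appeared where H3K27me3 was no longer called was asked next. Of the 12427 H3K27me3 regions called in Cas9 cells alone, 605 held an H3K27ac peak called in the knockout alone, or 4.87% (4.50 to 5.26), and 6 held one called in Cas9 cells alone. For H3K4me3 the numbers were 449, or 3.61% (3.30 to 3.96), and 155. Over random placement the knockout peaks were 8.18-fold enriched for H3K27ac and 12.8-fold for H3K4me3, while Cas9 peaks stood at 0.353-fold and 3.10-fold. The low H3K27ac value of Cas9 peaks follows in large part from H3K27ac and H3K27me3 seldom overlapping within Cas9 cells. Against shifts of up to 500 kb the knockout folds were smaller, 3.62 and 4.78, and the observed 605 and 449 regions still exceeded the highest of 1000 shifts, 205 and 126. Cas9 peaks stood at 0.15-fold and 1.41-fold of shifts, and for H3K4me3 the 155 regions exceeded the highest shift of 142. In the upper 50% of H3K27me3 scores, the H3K4me3 share was 6.21%.

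Seen from the active marks, 691 of 2843 H3K27ac peaks of the knockout alone, or 24.3% (22.8 to 25.9), lay in H3K27me3 regions of Cas9 cells alone. This compared with 7 of 685 peaks of Cas9 cells alone, or 1.02% (0.496 to 2.09), and 107 of 7269 knockout peaks shared with Cas9 cells, or 1.47% (1.22 to 1.78). Both of these classes were acetylated in Cas9 cells, where 1.61% of H3K27ac peaks overlapped H3K27me3, 0.236-fold of shifts. Their low shares thus follow in large part from how the classes were defined. For H3K4me3 the shares were 36.0% (33.6 to 38.6) of 1418 knockout peaks, 8.28% (7.17 to 9.54) of 2090 Cas9 peaks and 10.8% (10.3 to 11.3) of 12999 shared ones. Among H3K27me3 regions called in Cas9 cells alone, the highest-scoring with an H3K27ac peak of the knockout alone began with the first 3 named above. They were followed by chromosome 1 from 186535001 to 186564400 and chromosome 7 from 25713401 to 25742600. H3K27me3 regions called in both kinds of cell also held such peaks, with 3.93% (3.10 to 4.97) holding H3K27ac and 6.55% (5.46 to 7.83) holding H3K4me3 of the knockout alone. Over placement these were 4.13-fold for H3K27ac and 15.7-fold for H3K4me3, and over shifts 2.13-fold and 6.11-fold. Among the knockout regions shared with Cas9 cells, 4.79% (3.90 to 5.88) held H3K4me3 of the knockout alone, 21.8-fold over placement and 9.67-fold over shifts. For H3K27ac of the knockout alone the share was 2.48% (1.86 to 3.30), 5.00-fold over placement and 2.81-fold over shifts. The enrichment of both marks was thus not limited to regions where H3K27me3 was no longer called.

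H3K4me3 peaks that also carried H3K27me3, called bivalent, were compared as a class. They made up 1796 of 14363 peaks in Cas9 cells, or 12.5% (11.97 to 13.1), and 296 of 14417 in the knockout, or 2.05% (1.83 to 2.30). Shifts of up to 500 kb alone gave medians of 7.39% and 1.14%, so the folds over shifts were 1.69 and 1.79. Random placement gave medians of 3.57% and 0.971%, and the fold over placement was lower in the knockout. Overlap by position alone was thus also lower with the shorter H3K27me3 list of the knockout, and the enrichment over shifts did not fall. Most bivalent peaks of Cas9 cells kept H3K4me3, at 88.1% (86.5 to 89.5), while 9.30% (8.04 to 10.7) had H3K27me3 in the knockout. In the upper 50% of H3K4me3 scores, bivalent peaks made up 5.65% in Cas9 cells and 0.888% in the knockout.

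H3K27ac was called in the knockout at 615 of 1670 Cas9 peaks with H3K27me3 and without H3K27ac, or 36.8% (34.5 to 39.2). Among 5579 peaks with neither mark the share was 25.9% (24.7 to 27.03). The median score of the H3K4me3 peaks was 16 and 17 in these classes, and the median length 448 and 386 bp. H3K4me3 itself was called again in the knockout at 87.2% (85.6 to 88.8) of the former and 70.1% (68.9 to 71.3) of the latter. Among peaks where it was, the H3K27ac shares were closer, at 41.5% (39.0 to 44.1) and 34.3% (32.8 to 35.8). Among peaks with exactly 1 partner in the knockout they were 41.4% (38.6 to 44.2) and 35.7% (34.03 to 37.3). These last 2 comparisons were chosen after the data were seen. Since the knockout H3K27ac list was longer, it was also trimmed by score to the 7951 peaks of the Cas9 list, which gave 23.4% and 13.2%. The shares were 75.7% and 55.5% in the upper 50% of H3K4me3 scores. Of peaks already acetylated in Cas9 cells without H3K27me3, 93.8% (93.2 to 94.3) were acetylated in the knockout.

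**Figure D4:**
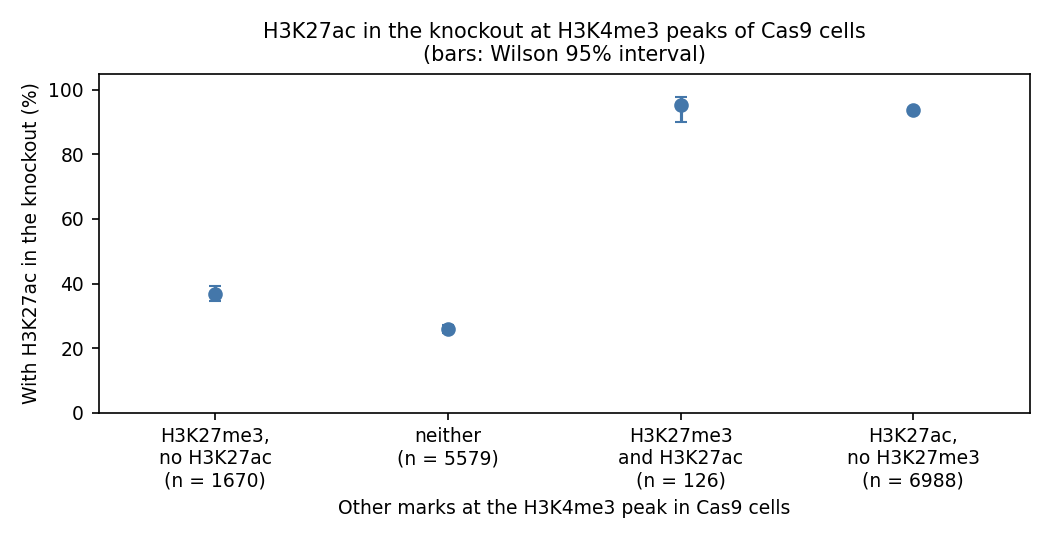
Percent of Cas9 H3K4me3 peaks with H3K27ac in the knockout (vertical axis) by the other marks the peak carried in Cas9 cells (horizontal axis), with Wilson 95% intervals. Peaks with H3K27me3 and no H3K27ac stand at 36.8%, above the 25.9% of peaks with neither.

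In neurospheres the Cas9 antibody gave short lists, of 2966 regions in cells labelled U6, 916 in Suz12F1 and 1048 in Suz12F2. Suz12 is another subunit of Polycomb repressive complex 2. The U6 and Suz12F2 lists often lay at H3K4me3 peaks of Cas9 tumour cells, with 49.2% (47.4 to 51.0) and 64.0% (61.1 to 66.9) of their regions there. The Suz12F1 list had 0.764% (0.371 to 1.57) there, 0.389-fold of random placement. At H3K27me3 regions of Cas9 tumour cells the lists were closer, with 25.3% (23.8 to 26.9) for U6, 16.8% (14.5 to 19.4) for Suz12F1 and 24.5% (22.01 to 27.2) for Suz12F2. For Suz12F1 this was 3.28-fold over placement and 1.56-fold over shifts of up to 500 kb, above the highest shift of 13.4%. U6 regions overlapped 42.7% (39.8 to 45.8) of the Suz12F2 list and 1.53% (0.913 to 2.55) of the Suz12F1 list. These were 56.0-fold and 2.00-fold over placement, and 24.2-fold and 1.17-fold over shifts of up to 500 kb. The Suz12F1 share lay within the ranges of both, which were 0 to 1.86% and 0.328 to 2.40%.

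Regions in both Suz12 lists numbered 8, of which 4 were also in U6 and 4 were not. The 4 outside U6 lay on chromosome X from 73843801 to 73844600, chromosome 16 from 3238201 to 3242600, chromosome 17 from 15447401 to 15450000 and chromosome 14 from 37030401 to 37032800, and they are named because of their small number, after their values were seen. The highest-scoring region of Suz12F1, on chromosome 11 from 3025401 to 3100400, was called in all 5 neurosphere lists, as were chromosome 17 from 39979801 to 39985800 and chromosome 14 from 61787001 to 61790800. Called with both antibodies, these 3 regions cannot be read as specific to either. No filter for regions of high background was applied here. The highest-scoring region of Suz12F1 absent from U6 lay on chromosome 1 from 90108001 to 90166800, and that of Suz12F2 on chromosome 4 from 70039001 to 70042200. The U6 overlap of Suz12F1 was 2.40% in the upper 50% of scores, where 2 regions were in both Suz12 lists and outside U6. With lists of equal number, the U6 overlap of Suz12F2 was 24.0%.

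The Gfi1 antibody, against a zinc finger transcriptional repressor, gave long lists that overlapped each other. There were 63177 regions over 367.9 Mb in Cas9 neurospheres and 67079 over 294.0 Mb in Suz12F2 neurospheres, a covered length ratio of 0.799. Of the Cas9 regions 76.1% (75.8 to 76.5) were overlapped, and of the Suz12F2 regions 81.4% (81.1 to 81.7), with 244.2 Mb in common. Over placement these shares were 3.26-fold and 3.37-fold, and over shifts of up to 500 kb 1.66-fold and 1.66-fold. Regions found with the Cas9 antibody overlapped 5.00% (4.83 to 5.17) and 4.72% (4.56 to 4.88) of the lists. In the other direction, most regions of these shorter lists lay in Gfi1 antibody regions of Cas9 cells, with 73.8% (72.2 to 75.4) for U6, 63.4% (60.3 to 66.5) for Suz12F1 and 79.3% (76.7 to 81.6) for Suz12F2. Over shifts these shares were 1.84-fold, 1.38-fold and 1.94-fold.

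The highest-scoring Gfi1 regions called in both were on chromosome 11 from 3020201 to 3100200, chromosome 1 from 90108001 to 90207800 and chromosome 17 from 39979801 to 39986000. All 3 were also called with the Cas9 antibody, so they cannot be read as specific to Gfi1. Outside Cas9 antibody regions the highest-scoring shared regions lay on chromosome 5 from 125476201 to 125581200 and chromosome 11 from 118330201 to 118443400. The highest-scoring region of Cas9 neurospheres alone lay on chromosome 5 from 136934201 to 136959200, and that of Suz12F2 alone on chromosome 17 from 13739401 to 13746200. The latter also overlapped a Cas9 antibody region of cells labelled U6. The share in Cas9 antibody regions was 1.75% and 2.03% when 50% of a region had to be covered, and 7.56% and 8.19% in the upper 50% of scores.

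Gfi1 antibody regions were last set against the tumour marks, which come from other cells. Of tumour H3K27ac peaks in Cas9 cells, 87.1% (86.4 to 87.8) lay in Gfi1 regions of Cas9 neurospheres and 98.9% (98.7 to 99.1) in those of Suz12F2 neurospheres. For H3K4me3 these were 86.4% (85.8 to 87.0) and 97.5% (97.2 to 97.7), and for H3K27me3 79.8% (79.1 to 80.4) and 75.4% (74.6 to 76.1). Since the Gfi1 lists are long, shifts of up to 500 kb alone gave median shares of 35.6% and 30.5% for H3K27ac, 36.97% and 31.9% for H3K4me3 and 58.4% and 52.9% for H3K27me3. H3K27ac peaks of the knockout alone were overlapped at 89.3% (88.1 to 90.4) and 98.4% (97.9 to 98.8), close to the 87.5% and 99.1% of knockout peaks shared with Cas9 cells.

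From the Gfi1 side, 17.2% (16.9 to 17.5) of regions in Cas9 neurospheres overlapped tumour H3K27me3 of Cas9 cells, 8.74% (8.52 to 8.96) H3K27ac and 14.1% (13.9 to 14.4) H3K4me3. In Suz12F2 neurospheres the shares were 17.0% (16.7 to 17.2), 9.54% (9.32 to 9.76) and 15.5% (15.2 to 15.7). With the marks of the knockout they were 5.09%, 11.01% and 14.4% in Cas9 neurospheres and 4.55%, 11.9% and 15.6% in Suz12F2 neurospheres. Over random placement the folds for H3K27me3, H3K27ac and H3K4me3 of Cas9 cells were 2.91, 4.81 and 4.54 in Cas9 neurospheres and 3.20, 6.75 and 6.26 in Suz12F2 neurospheres. Over shifts of up to 500 kb, which keep the neighbourhood, the folds were lower, at 1.35, 2.45 and 2.34, and 1.41, 3.27 and 3.05. For H3K27me3 of the knockout, whose list is shorter, the folds were 2.48 and 2.57 over placement in Cas9 and Suz12F2 neurospheres. Over shifts they were 1.27 and 1.32. When 50% of a Gfi1 region had to be covered, the Cas9-cell shares were 10.9%, 0.627% and 2.64%, and 12.1%, 0.748% and 3.69%. In the upper 50% of scores of the Suz12F2 list, 16.4% overlapped H3K27ac and 26.02% H3K4me3.

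**Figure D5:**
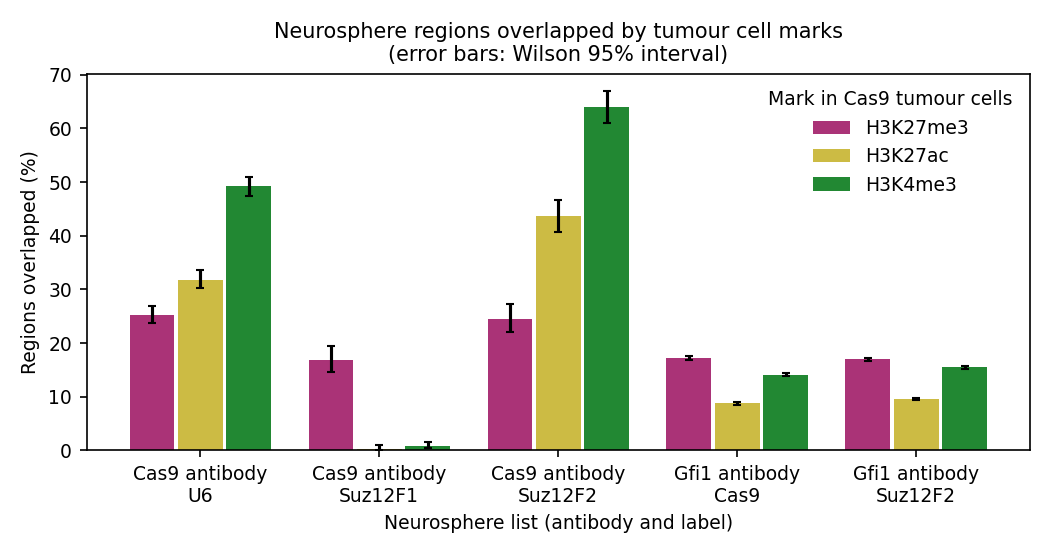
Percent of regions in each of 5 neurosphere lists (horizontal axis) overlapped by H3K27me3, H3K27ac or H3K4me3 regions of Cas9 tumour cells (vertical axis), with Wilson 95% intervals. The Suz12F1 list stands apart at H3K4me3, with 0.764% against 49.2% for U6 and 64.0% for Suz12F2, and less so at H3K27me3, with 16.8% against 25.3% and 24.5%.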

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

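The shifts of up to 500 kb, the removal of Cas9 antibody regions from tumour lists, their removal without Suz12F1, the equal numbers of Cas9 antibody regions and those of H3K27ac peaks at H3K4me3 peaks were chosen after the result was seen. Over 46 results, 74 alternative values stayed within the counting interval of a share or within 1.5 times of a count, ratio or fold, 117 moved beyond that and 2 changed side of a ratio of 1. In long lists the counting interval is narrow, so a small move can exceed it. The covered length of H3K27me3 stayed lower in the knockout, and that of H3K27ac higher, under all alternatives run for them. Depth is unknown and limits all comparisons of list size. No paired analysis was possible because each group held 1 library and no test across samples was fitted. The alternatives for promoters were not run, since an mm9 annotation was not used here. Where no construction explains a move, the cause was not tested.

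With 50% of a tumour region covered, the overlapped share was 6.40% of Cas9 regions and 27.5% of knockout regions for H3K27me3, 89.6% of Cas9 regions and 67.7% of knockout regions for H3K27ac, 79.0% of Cas9 regions and 86.6% of knockout regions for H3K4me3. In the upper 50% of scores, the overlapped share was 10.0% of Cas9 regions and 29.3% of knockout regions for H3K27me3, 92.4% of Cas9 regions and 73.0% of knockout regions for H3K27ac, 87.5% of Cas9 regions and 88.3% of knockout regions for H3K4me3. With equal numbers by score, the overlapped share was 17.1% of Cas9 regions and 20.5% of knockout regions for H3K27me3, 83.2% of Cas9 regions and 82.5% of knockout regions for H3K27ac. Merged within 5 kb, the overlapped share was 14.1% of Cas9 regions for H3K27me3, 94.7% of Cas9 regions and 75.5% of knockout regions for H3K27ac, 93.8% of Cas9 regions and 93.0% of knockout regions for H3K4me3. At 1 kb or more, which leaves few narrow peaks, the overlapped share was 70.6% of Cas9 regions and 56.3% of knockout regions for H3K27ac, 55.2% of Cas9 regions and 84.8% of knockout regions for H3K4me3. Outside Cas9 antibody regions, the overlapped share was 10.7% of Cas9 regions and 29.8% of knockout regions for H3K27me3, 90.4% of Cas9 regions for H3K27ac, 84.2% of Cas9 regions and 89.4% of knockout regions for H3K4me3. The H3K27me3 covered length ratio was 0.414 with equal numbers, and the H3K4me3 number ratio, 1.00 as deposited, was 0.653 at 1 kb or more and 0.996 outside Cas9 antibody regions.

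H3K27me3 regions of Cas9 cells alone held H3K27ac and H3K4me3 of the knockout alone at 6.58% and 6.21% in the upper 50% of scores and 7.26% and 5.20% when merged, which makes regions longer. Their folds were 3.62 and 4.78 over shifts, which keep the neighbourhood. In the upper 50% of H3K4me3 scores, bivalent peaks made up 5.65% in Cas9 cells and 0.888% in the knockout, and H3K27ac was called at 75.7% of peaks with H3K27me3 and 55.5% without. With equal numbers of H3K27ac peaks and all H3K4me3 scores, where the shares as deposited were 36.8% and 25.9%, they were 23.4% and 13.2%. The U6 overlap of Suz12F2 was 29.7% at 50% cover, 38.5% in the upper 50% of scores and 24.0% with equal numbers, and 2 regions in the upper 50% of scores were in both Suz12 lists and outside U6.

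Between the Gfi1 lists, the overlapped shares of Cas9 and Suz12F2 regions were 64.7% and 78.1% at 50% cover, 74.1% and 79.0% in the upper 50% of scores, 74.5% and 84.1% with equal numbers, 74.7% and 79.0% outside Cas9 antibody regions and 74.9% and 79.6% outside those of U6 and Suz12F2, and 81.8% of Suz12F2 regions on autosomes. Their shares in Cas9 antibody regions were 1.75% and 2.03% at 50% cover, 7.56% and 8.19% in the upper 50% of scores and, for Suz12F2, 4.96% with equal numbers. Shares of Gfi1 regions with tumour marks follow, in the order H3K27me3, H3K27ac and H3K4me3. Cas9 neurospheres with Cas9 tumour marks had 10.9%, 0.627% and 2.64% at 50% cover and 24.8%, 10.2% and 17.7% in the upper 50% of scores. They had 16.2%, 7.20% and 11.8% outside Cas9 antibody regions and 16.4%, 7.17% and 11.8% outside those of U6 and Suz12F2. Cas9 neurospheres with knockout tumour marks had 2.37%, 0.755% and 1.98% at 50% cover and 7.25%, 13.4% and 18.1% in the upper 50% of scores. They had 4.73%, 9.03% and 12.0025% outside Cas9 antibody regions and 4.78%, 8.99% and 11.97% outside those of U6 and Suz12F2. Suz12F2 neurospheres with Cas9 tumour marks had 12.1%, 0.748% and 3.69% at 50% cover and 24.0%, 16.4% and 26.02% in the upper 50% of scores. They had 16.1%, 8.07% and 13.3% outside Cas9 antibody regions and 16.2%, 8.04% and 13.2% outside those of U6 and Suz12F2. Suz12F2 neurospheres with knockout tumour marks had 2.55%, 0.960% and 2.68% at 50% cover and 6.05%, 20.5% and 26.5% in the upper 50% of scores. They had 4.22%, 10.0% and 13.4% outside Cas9 antibody regions and 4.26%, 9.98% and 13.3% outside those of U6 and Suz12F2. Over shifts the folds with marks of Cas9 cells were 1.35, 2.45 and 2.34 for Cas9 neurospheres and 1.41, 3.27 and 3.05 for Suz12F2 neurospheres.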

Other observations

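The tests of H3K27ac sensitivity, of weak H3K27me3 regions, of spreading next to former regions, of copy number and of the Suz12 label were chosen after the result was seen, as were the peak widths, the score quartiles and the rule for reading the copy number correlation.

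Peak widths changed differently at bivalent sites. Among H3K4me3 peaks with exactly 1 partner in the other cells, the median ratio of knockout to Cas9 width was 0.889 (quartiles 0.743 and 1.02) for 8877 peaks without H3K27me3 in Cas9 cells. It was 1.03 (quartiles 0.845 and 1.34) for 1298 peaks with it. The share wider in the knockout was 27.5% (26.5 to 28.4) without H3K27me3 and 55.8% (53.1 to 58.5) with it. Of 109 H3K27ac peaks inside H3K27me3 regions of Cas9 cells, 88.1% (80.7 to 92.9) were wider in the knockout, with a median ratio of 1.58. For the 6595 others the share was 60.1% (58.9 to 61.3) and the ratio 1.05. At bivalent sites without H3K27ac in Cas9 cells, H3K4me3 was wider in 59.0% (54.7 to 63.3) of 498 peaks with H3K27ac in the knockout and in 54.6% (50.9 to 58.3) of 705 without it. Widths depend on the peak caller and on library depth, and these are differences between 2 libraries.

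H3K27ac peaks called in the knockout alone often lay in former H3K27me3 regions. From the lowest to the highest score quartile, 20.8%, 20.1%, 22.4% and 33.9% of them did. If the knockout list were more sensitive alike at all sites, H3K27me3 regions of Cas9 cells would make no difference at equal score. Peaks of the same score decile would be called in Cas9 cells as often inside as outside them. This was 13.7% (11.6 to 16.1) of 906 inside against 64.4% outside, 4.71-fold lower, and 38.3% against 93.2% in the upper 50% of scores. Within Cas9 cells, however, only 1.61% of H3K27ac peaks overlapped H3K27me3, 0.236-fold of shifts. Grouping peaks by H3K27me3 of Cas9 cells thus selects sites seldom acetylated there, so the comparison cannot decide on sensitivity. Neighbourhoods shared by both marks do not alone account for the pattern. After shifts of up to 500 kb, 183 (143 to 218) peaks lay there, against 691 observed, 3.78-fold. Shifts also move peaks off H3K4me3 sites, while 82.8% of these peaks lay at H3K4me3 peaks of Cas9 cells. Whether both marks only share H3K4me3 sites is thus not settled by shifts. At H3K4me3 peaks of Cas9 cells without H3K27ac, the knockout had H3K27ac at 36.8% with H3K27me3 and 25.9% without. Among those whose H3K4me3 was called again in the knockout, the shares were closer, at 41.5% and 34.3%. Release of former H3K27me3 sites by loss of Ezh2 remains a hypothesis. With 1 library per group it cannot be told apart from a difference between libraries, including one in sensitivity, at all sites or at these alone.

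H3K27me3 regions called in the knockout alone made up most of the knockout list. Weak regions near the threshold are a candidate explanation, since among regions of the same length the share was 57.1% (55.2 to 58.9) at upper scores and 74.5% (72.8 to 76.1) at lower ones. Spreading next to former regions stays open: 24.1% lay within 10 kb of a Cas9 region against 16.6% (14.7 to 18.6) of shifted copies that, like them, overlapped none, 1.45-fold, above every shift but under the 1.5-fold set for this explanation. Copy number stays open: over 19 autosomes, which are not replicates, the knockout-to-Cas9 ratios of H3K27me3 and H3K4me3 numbers gave Spearman's rho 0.115 (-0.358 to 0.541, permutation p = 0.639, adjusted p = 0.768) and Pearson's r 0.073 (permutation p = 0.768, adjusted p = 0.768), with r 0.106 without 2 chromosomes, in a family of 4 tests. With H3K27ac in place of H3K4me3 rho was -0.119 (permutation p = 0.625, adjusted p = 0.768) and r -0.111 (permutation p = 0.655, adjusted p = 0.768), with r 0.019 without 2 chromosomes.

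The Cas9 antibody list labelled Suz12F1 stood apart from U6 and Suz12F2 at tumour H3K4me3 peaks, and less so at tumour H3K27me3 regions. A stricter call would bring the other lists down to its level, but their highest-scoring 916 regions lay at tumour H3K4me3 peaks in 59.4% (56.2 to 62.5) and 62.0% of cases. Whether the Suz12 label plays a part stays open, since the 64.0% of Suz12F2 belongs to the pattern and each label had 1 library. A difference in antibody yield or background between libraries cannot be told apart from a difference between the cells, since 1 library carried the Suz12F1 label.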
